A study of Mus musculus with 2 samples.

How the data were processed

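Gene expression was measured on 2 two-colour oligonucleotide arrays, 1 for epidermis and 1 for dermis of mice at postnatal day 3. Skin had been split into both layers with the protease dispase at 2.4 U/ml and 4 °C overnight, per the labels' protocols. Each array carried RNA of Casp-8 F/+ K5-Cre mice labelled with the dye Cy3 and RNA of Casp-8 F/– K5-Cre mice labelled with the dye Cy5. RNA of 3 mice was pooled in each channel, except for the Casp-8 F/– K5-Cre dermis, which was a pool of 2 mice. The labels give no dye swap and no second array of either tissue, so there is 1 sample per tissue.

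The deposited scanner files hold 1 dye of 1 array each, 4 in all, as pixel intensities of every spot and of its local background, quantified with a fixed circle by a program at version 5.0, per the file headers. Signal and background stand in separate columns, and no subtraction or normalization of these intensities is recorded, per the file headers. The dye of each file was taken from the image name in its header. The authors also deposited a table with 1 value per feature and array. Set against the scanner signals, with features numbered down the array's columns, these values were log10 ratios of Cy5 over Cy3. Within the lower 9 of 10 intensity deciles their slope against the log2 ratio of the signals ran from 0.296 to 0.304 for the epidermis and from 0.287 to 0.301 for the dermis, where a log10 scale gives 0.301, and r was at least 0.973. In the brightest decile r was only 0.654 for the epidermis and 0.624 for the dermis, so the deposited values departed from the unnormalized signals there. The numbering was borne out by the fact that none of the control spots or spots without an ID had a value in that table. Column medians were -0.0025 (epidermis) and 0.0014 (dermis). Direction and scale were thus settled from the values. The authors had centred these log10 ratios before they deposited them, as far as the values show, since without normalization the median log2 ratios of the signals were -0.56 and -0.47. How the authors normalized or filtered them is not given in the sources used here.

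Each array holds 22575 spots, of which 21318 are spots of 20868 named probes. The files give an array manufacturer's probe number for each spot and pair none of them with a gene, and the gene table at hand lists no such numbers (0 matched). Results are therefore given by probe. The 38 gene lists and the marker lists of skin cell types that had been fixed before the data were examined could not be applied, Casp8 itself could not be looked up, and the rule for named genes, which asked for gene symbols, named none. In its place the 2 highest and the 2 lowest probes of each tissue are named, by their log2 ratio, with the few probes that a small count refers to, chosen after their values were seen.

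Ratios were computed in R 4.3.3 with limma 3.58.1. Mean pixel signals were corrected for the local background median with normexp and an offset of 50, and Cy5 over Cy3 was normalized within each array by loess with a span of 0.3, in which control spots and spots without an ID had weight 0. Spots of a probe were averaged. A probe was measured where the signal exceeded the mean local background by 2 of its SDs in at least 1 channel. This rule removed no probe, and 100% of the negative control spots passed it too, so a stricter limit at the 95th percentile of the 162 negative control spots was tried as well. Where the dimmer signal of a named probe did not exceed that limit, its fold was given as at least the brighter level over the higher of 2 normalized levels in the dim channel, the probe's own and the lowest among probe spots above the limit. For A_51_P145453 in the epidermis its own level was the higher, so that bound equals the measured fold. Signals of 65000 or more were taken as at the scanner's upper limit. A probe was called higher or lower where its ratio reached 2-fold. No significance test was run and no p-value is given, because 1 array per tissue leaves no estimate of the spread between mice or pools. The only error that could be measured was that between the 10 spots of each of 50 probes on one array, which is technical. Levels in epidermis and dermis were compared within one dye after quantile normalization of mean intensities between the arrays.

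With both arrays labelled the same way round, the preference of a probe for one dye cannot be separated from the genotype on either array. It drops out of the difference between the tissues only where it is equal on both arrays. This was not tested, and it need not hold for a preference that depends on intensity. The offset also shrinks the ratios of dim probes. In simulated arrays with known changes in 200 of 20868 probes, 82 of 100 probes changed 3-fold and 100 of 100 changed 8-fold were recovered for the epidermis, against 89 of 100 and 100 of 100 for the dermis. The median recovered fold of the 8-fold probes was 6.19 and 6.17, and 0 of 20668 unchanged probes were called on either array. That 0 followed from the setting, since the simulated noise was only the SD between replicate spots, far inside the 2-fold limit. Uneven spots and a bend left at the bright end were not simulated, so it is no error rate for the real arrays.

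Alternatives covered the background correction, median pixels, other normalizations, filters on dim and saturated spots, other fold thresholds and the authors' table. Leaving out the brightest 2% of probes, a loess span of 0.1, a loess fit without saturated spots, the limit from the negative controls, and leaving out spots whose pixel SD exceeded 0.5 times their mean were chosen after seeing the data. No replicate could be left out.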

Results

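The skin of newborn mice was compared between Casp-8 F/– K5-Cre and Casp-8 F/+ K5-Cre animals, separately for epidermis and dermis. Casp-8 is caspase-8, a protease of the death receptor pathway. K5-Cre is Cre recombinase under the keratin 5 promoter, which is active in basal keratinocytes, and F conventionally marks an allele that Cre can inactivate. F/– animals can thus lose both copies in keratinocytes, whereas F/+ animals keep a wild-type copy. The – and + alleles belong to the genotype of the whole animal, so dermal cells differ in them too. The groups of animals are called F/– and F/+ from here on. The question, as the series title puts it in other words, was in which layer of the skin mRNA levels differ between the genotypes. Ratios are F/– over F/+ throughout.

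Median probe signals on the epidermis array were 501 in Cy3 and 311 in Cy5, over median local backgrounds of 39.5 and 32.0. On the dermis array they were 546 and 364, over 39.0 and 33.0. Between 95.4% and 97.9% of probe spots lay above the 95th percentile of the negative controls, depending on array and dye. In Cy5, 34 probe spots on the epidermis array and 4 on the dermis array were at the scanner's upper limit, and in Cy3 none were. Over the 50 probes printed 10 times each, the pooled SD of the log2 ratio between spots was 0.079 on the epidermis array and 0.050 on the dermis array. The 2-fold limit thus lay 12.6 and 20.1 such SDs from 0. This spread covers spot noise only. It does not cover differences between mice, between pools or between the dyes, and the number of arrays limits the precision.

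In the epidermis, 195 of 20868 probes read at least 2-fold higher in F/– and 63 at least 2-fold lower, 1.24% of all probes. Of the higher probes, 86 belonged to the brightest 2% of the array, where the median of all 418 probes was itself 0.35 on the log2 scale, and 0 of the lower ones did. Outside the brightest 2%, 109 probes were higher and 63 lower, so that the share of higher probes among those changed was 63.4% rather than 75.6%. In the authors' deposited table, 141 probes were at least 2-fold higher and 100 lower, a share of 58.5%. Without normalization the share was 7.39%. Of the 109 higher probes outside the brightest 2%, 100 were also past 2-fold in the authors' deposited table (101 had a value there), whereas only 4 of the 86 bright ones were.

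The highest epidermal ratios were those of probe A_51_P386870, at 5.66 on the log2 scale or 50.5-fold, and probe A_51_P402943, at 5.39 or 41.8-fold. Background-corrected signals of A_51_P386870 were 254 in F/+ and 9424 in F/–, and those of A_51_P402943 were 1166 and 33489. For A_51_P402943 the authors' deposited table has 4.71 on the log2 scale, and without normalization the ratios of both probes were 4.98 and 4.79. Both were also past 2-fold in the dermis, with log2 ratios of 1.13 and 1.34, but not without normalization, where they had 0.60 and 0.95 and the median of all probes was -0.47. The lowest ratio was that of A_51_P145453, at least 73.3-fold lower in F/– epidermis, with a signal of 8799 in F/+ and one of 28.2 in F/– that did not exceed the 95th percentile of the negative controls. Normexp with offset 0 gave -7.68 on the log2 scale, and the authors' deposited table has -7.48. The same probe was 4.05-fold lower in the F/– dermis (log2 ratio -2.02, or -2.86 with offset 0). The second lowest, A_51_P375138, had a log2 ratio of -4.62, but its Cy3 pixels varied by 1.33 times their mean, against a median of 0.066 for probe spots in that channel. With median pixel signals its ratio was -2.63. The authors' deposited table gives no epidermal value for it. Among the 50 probes with 10 spots each, 2 passed 2-fold in the epidermis. A_51_P112223 had a log2 ratio of 1.65 ± 0.075 (SD, n = 10 spots of 1 array) there and 0.27 ± 0.077 in the dermis, and A_51_P475138 had 1.04 ± 0.082 and 0.024 ± 0.065. For these 2 probes the difference between the tissues was larger than the spread between spots.

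**Figure D1:**
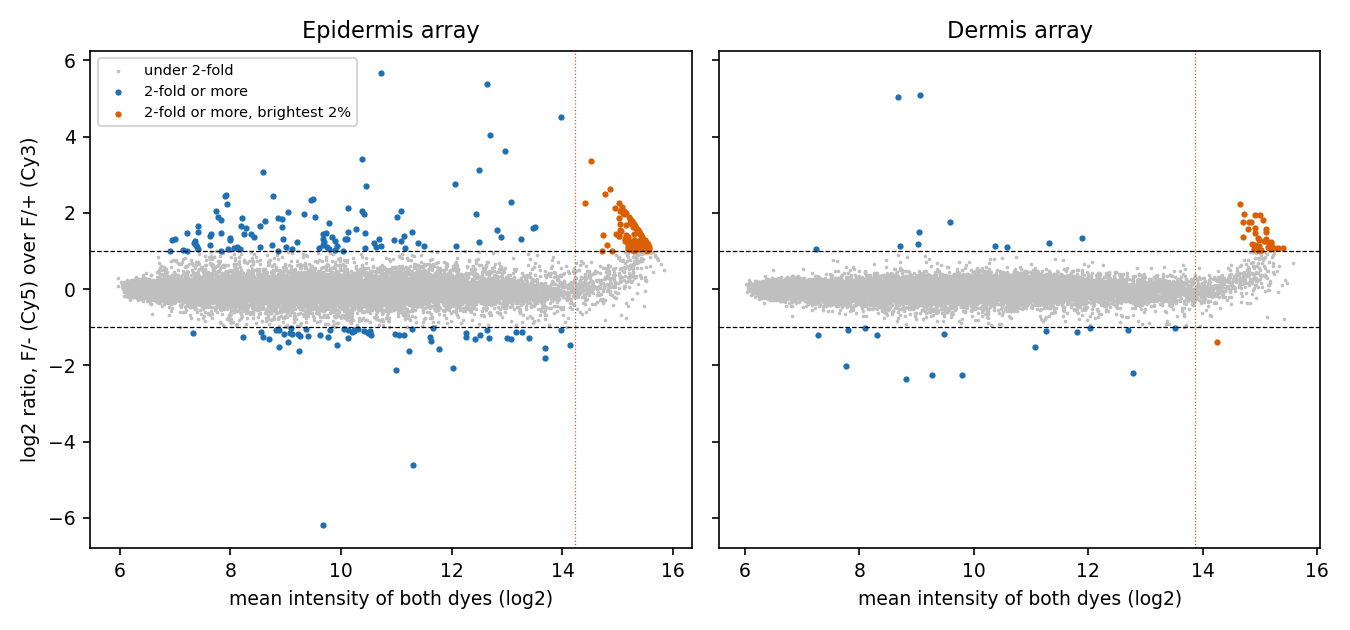
Log2 ratio of F/– over F/+ against the mean log2 intensity of both dyes, 1 point per probe, for the epidermis array (left) and the dermis array (right). Dashed lines mark 2-fold and the dotted line the brightest 2%, which held 86 of 195 higher probes in the epidermis and 38 of 49 in the dermis.

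In the dermis, fewer probes reached 2-fold. Of 20868 probes, 49 read higher and 17 lower in F/–, 0.32% of all. The brightest 2% held 38 of the 49 higher probes and 1 of the lower ones, and their median log2 ratio was 0.17. Without them 11 probes were higher and 16 lower, a share of higher probes of 40.7% rather than 74.2%. That share includes lower calls from uneven spots. Without spots whose pixel SD exceeded 0.5 times their mean, and outside the brightest 2% of either array, 11 were higher and 9 lower. The authors' deposited table has 15 probes at least 2-fold higher and 12 lower in the dermis, a share of 55.6%. With one median factor per array in place of loess the share was 88.8%, and without normalization it was 18.5%. All 11 higher probes outside the brightest 2% were also past 2-fold in the authors' deposited table, whereas 2 of the 38 bright ones were.

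A pair of probes stood apart in the dermis. A_51_P479715 was 33.8-fold higher in F/– (log2 ratio 5.08), with background-corrected signals of 63.8 in F/+ and 2532 in F/–. A_51_P402994 was at least 27.0-fold higher, with 39.7 and 1896, the F/+ signal lying below the 95th percentile of the negative controls. These folds depend on the offset at such dim signals. With offset 0 they were 64.2-fold and 82.0-fold, and the ratios in the authors' deposited table come to 56.7-fold and 65.9-fold. In the epidermis these probes had log2 ratios of 1.20 and 1.25, with F/+ signals of 2178 and 1720. Without normalization these epidermal ratios were 0.53 and 0.58, where the median of all probes was -0.56. The lowest dermal ratios, -2.36 for A_51_P301615 and -2.26 for A_51_P132079, came from spots whose Cy3 pixels varied by 1.56 and 1.35 times their mean, and neither has a dermal value in the authors' deposited table. With median pixel signals they were -0.96 and -0.92, under 2-fold. Of the 17 lower probes in the dermis, 7 came from spots with a pixel SD over 0.5 times the mean, and 10 remained without them. None of the 50 probes with 10 spots passed 2-fold in the dermis. The largest mean among them was that of A_51_P262079, at 0.53 ± 0.034 (SD, n = 10 spots), with 0.45 ± 0.043 in the epidermis.

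Across probes, the genotype ratios of both tissues were correlated, with a Pearson r of 0.31 and a Spearman rho of 0.24 over all 20868 probes, and 0.28 and 0.23 without the brightest 2% of either array. Probes are not independent replicates, and any dye preference shared by both arrays enters this correlation. At least 2-fold higher in both tissues were 33 probes, of which 27 were among the brightest, leaving 6. At least 2-fold lower in both were 6, of which 1 came from an uneven spot in the dermis. For lists drawn independently, the calls outside the brightest 2% of either array give an overlap of 0.059 higher and 0.045 lower probes. Of the 109 probes higher in the epidermis outside the brightest 2% of either array, 74 had a ratio above 0 in the dermis, where 48.2% of all such probes did, and their median dermal log2 ratio was 0.10. Of the 61 lower ones, 41 had a dermal ratio below 0, with a median of -0.26.

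**Figure D2:**
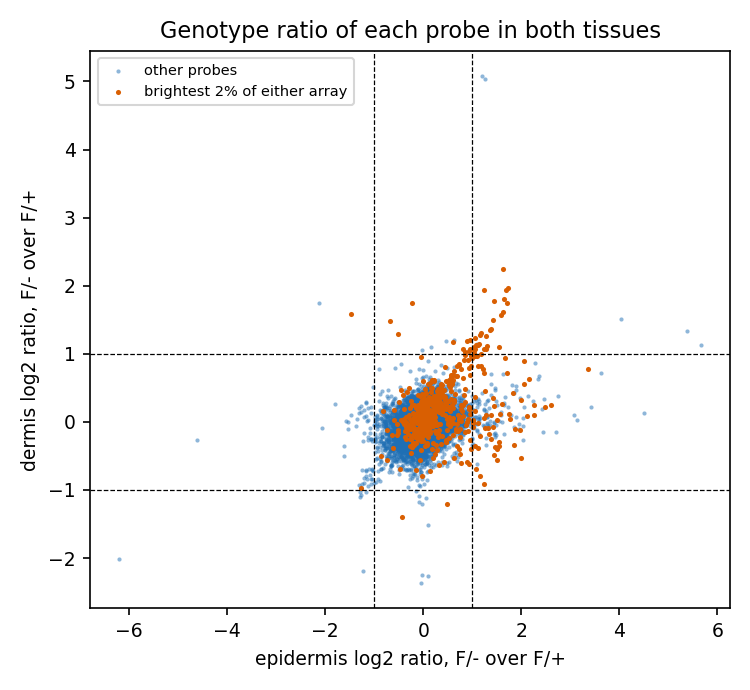
Log2 ratio of F/– over F/+ in the dermis against that in the epidermis, 1 point per probe, with dashed lines at 2-fold. The 33 probes past 2-fold in the upper right corner include 27 of the brightest 2% of either array (orange), and 6 probes lie in the lower left corner.

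The difference of the ratios, epidermis minus dermis, was at least 2-fold positive for 175 probes and at least 2-fold negative for 59. Without the brightest 2% of either array these counts were 116 and 55. A dye preference of a probe drops out of this difference only where it is equal on both arrays, which was not tested. The ratio of A_51_P386870 was higher in the epidermis by 4.52 on the log2 scale, and that of A_51_P479715 was higher in the dermis, with a difference of -3.88.

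Far more probes reached 2-fold between epidermis and dermis than between genotypes, but the measures are unlike. Tissue levels were compared between single channels of separate arrays, so differences between arrays enter them. Genotype ratios were taken within each spot. In F/+ skin, compared within Cy3, 2121 probes read at least 2-fold higher in epidermis and 2256 at least 2-fold lower, 21.0% of all probes, and 88 and 154 of them at least 16-fold. In F/– skin, compared within Cy5, the counts were 2118 and 2161. The tissue differences of both genotypes had a correlation of 0.96 across probes, with 1757 probes higher in epidermis in both genotypes, 1909 lower in both and 2 in opposite directions. Both channels were read from the same spots of the same arrays, so these are not independent comparisons. Without gene names, keratinocyte and fibroblast genes could not be used to check how cleanly the layers had been separated.

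The genotype ratios were also set against the tissue difference of each probe, taken as the mean of both dyes and without the brightest 2% of either array. The 110 probes at least 16-fold higher in dermis had a median dermal log2 ratio of -0.18, with quartiles of -0.42 and 0.022, and 27.3% of them lay above 0. The 55 probes at least 16-fold higher in epidermis had a median of 0.033, with quartiles of -0.058 and 0.12. On the epidermis array the medians of these groups were 0.013 and -0.056.

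**Figure D3:**
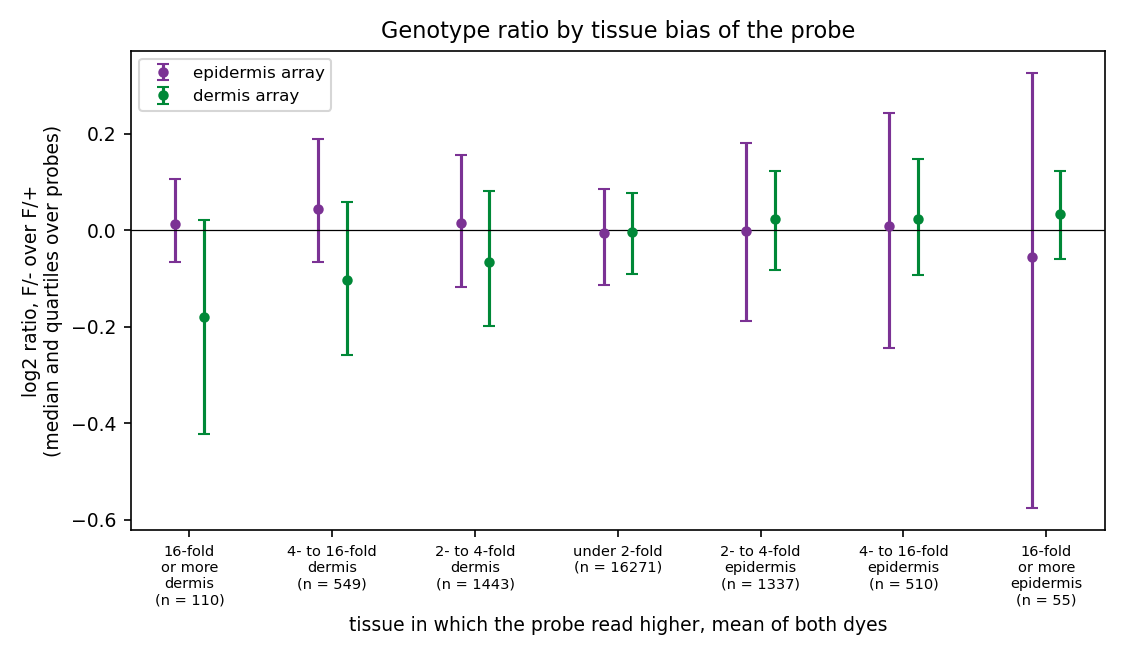
Median log2 ratio of F/– over F/+ on the dermis array and on the epidermis array, with bars for the quartiles over probes, in groups of probes by their level in epidermis against dermis. Medians on the dermis array run from -0.18 in the 110 most dermal probes to 0.033 in the 55 most epidermal ones.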

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

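No test was possible for any of these results, each of which rests on 1 array per tissue. They were singled out after the data were seen.

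Just 2 probes passed 2-fold in opposite directions in the 2 tissues, and this difference was not tested. A_51_P389265 had a log2 ratio of -2.13 in the epidermis and 1.75 in the dermis, a difference of -3.87, with background-corrected signals of 5355 (F/+) and 726 (F/–) in the epidermis and 452 and 1124 in the dermis. The authors' deposited table has it at -2.19 and 1.86. A_51_P374469 had -1.47 and 1.58, a difference of -3.05, but it belonged to the brightest 2% in the dermis, and the authors' deposited table gives it a dermal value of 0.74, under 2-fold.

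Spots without an ID, 521 on each array, were not used in any comparison. Above the 95th percentile of the negative controls lay 19.6% of them in Cy3 on the epidermis array and 19.2% in each of the other channels. The same spots stood out on both arrays, with 99 above the limit in at least 1 dye on each, and none of them reached a 2-fold ratio. Other control spots, 574 on each array, were above that limit in 54.7% (Cy3) and 55.1% (Cy5) of cases on the epidermis array and in 51.9% and 52.8% on the dermis array, and none of those above it reached 2-fold either.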

How the results depend on the processing

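The loess span of 0.1, the loess fit without saturated spots and leaving out the brightest 2% or uneven spots were added after the data were seen. Without normalization, epidermis counts were 92 higher and 1153 lower, 224 probes were lower in the dermis, 16 were higher and 85 lower in both tissues, and 110 had a ratio lower in epidermis than dermis; the medians of all probes then lay at -0.56 and -0.47 on the log2 scale, so these counts follow the dyes' overall balance. At 1.5-fold, counts were 521 higher and 386 lower in the epidermis, 119 and 144 in the dermis, 81 and 45 in both, and 567 and 332 for the difference between tissues; at 3-fold they were 68 and 7, 12 and 5, 6 and 1, and 63 and 13. The authors' deposited table gave 100 lower in the epidermis, 15 higher in the dermis, 6 higher in both and 92 with a ratio lower in epidermis. Leaving out the brightest 2% gave 109 higher in the epidermis, 11 in the dermis, 6 in both and 116 for the difference; a loess span of 0.1 gave 30 higher in the dermis and 15 in both; and one median factor per array gave 103 higher in the dermis, with 64 higher and 3 lower in both. Normexp with offset 0 gave 102 lower in the epidermis and 90 with a lower ratio than in the dermis, where only the offset differs. Plain subtraction, which changes the background method as well, gave 97 lower in the epidermis. Without uneven spots, 10 probes were lower in the dermis. Thresholds and left-out probes change the counts by construction; for plain subtraction, the authors' table, the narrower span and the median factor the cause was not tested. In F/+ skin, median scaling of the channels gave 2492 probes higher and 1979 lower in epidermis, within 1.5 times the counts with quantile normalization. The Cy5 channel, which holds F/– RNA and is a comparison of its own, gave 2118 and 2161. The Pearson r between the arrays stayed between 0.26 and 0.35 under all normalizations and filters run. The planned filter in both channels removed 1 epidermal probe and so tested little. The limit from the negative controls, also added later, removed 747 probes on the epidermis array and 394 on the dermis array, with calls per tissue as before and 174 and 58 for the difference. Of 234 alternative log2 ratios of the 8 named probes, 168 moved by less than the SD between spots, 66 by more, and none that was past 2-fold changed sign. Without normalization 4 of them were no longer past 2-fold, those of A_51_P386870 (0.60) and A_51_P402943 (0.95) in the dermis and of A_51_P479715 (0.53) and A_51_P402994 (0.58) in the epidermis. With median pixel signals the dermal calls of A_51_P301615 and A_51_P132079 ended as well, and the uneven probes came to -2.63 (A_51_P375138, epidermis), -0.96 (A_51_P301615, dermis) and -0.92 (A_51_P132079, dermis). Not run were the brightest probe per gene and all alternatives for gene lists, since no probe has a gene name here. No spot carried a flag, so that choice changed saturated spots only. Dim signals limit the ratios: of 34 simulated 3-fold changes at a mean log2 intensity of 8 or less on the epidermis array, 16 were recovered.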

Other observations

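The tests on bright probes' median, on the loess fit without spots at the upper limit and on carry-over were chosen after the values they bear on had been seen in part; the tests on the share of spots at the upper limit, spot noise and spatial trends were fixed before their results.

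Probes lower in the F/– dermis were mostly probes that read higher in dermis than in epidermis. Outside the brightest 2% of either array, 10.7% of all 20275 probes read at least 2-fold higher in dermis within F/+ skin, whereas 12 of the 15 probes lower in the F/– dermis did, and 9 of the 15 within F/– skin. Without probes uneven on either array it was 6 of 8 in either genotype. In the epidermis the class of the changed probes depended on the channel that defines it. Of the 109 probes higher in F/– epidermis, 20 were epidermal and 35 dermal by F/+ levels, against 57 and 12 by F/– levels, into which the change itself enters. The level and the ratio come from the same arrays, and no test was possible.

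The dermal genotype ratio rose with the tissue bias of a probe (Spearman rho of 0.15 across probes with the mean of both dyes, 0.20 with F/+ levels and 0.082 with F/– levels). For the epidermal ratio the sign depended on the channel (-0.0052, -0.11 and 0.095). The dermal trend came mostly from dermal probes. The 110 probes at least 16-fold higher in dermis had a median dermal log2 ratio of -0.18, and those 4- to 16-fold higher had -0.10. In the authors' deposited table these medians were -0.15 and -0.097. A larger carry-over of epidermal RNA into the F/– dermis pool would raise the strongly epidermal probes together. The 55 probes at least 16-fold higher in epidermis had a median of 0.033, or 0.068 in the authors' deposited table. Both lay under the 0.1 taken as the limit, so the tables argue against carry-over as the whole of the pattern. For the 11 probes higher in the F/– dermis the class depended on the channel. With the mean of both dyes, 5 read at least 2-fold higher in epidermis, against 9.38% of all, and 3 in dermis, against 10.4%. By F/+ levels 4 were epidermal and 4 dermal, and by F/– levels 3 and 4, so these counts do not decide on carry-over. On the log2 scale, A_51_P479715 and A_51_P402994 read 4.31 and 4.36 higher in F/+ epidermis than in F/+ dermis, as carry-over would need. In F/– skin, however, their normalized log2 levels in dermis were near those in epidermis, 11.5 against 11.9 and 11.1 against 11.7. Carry-over that large would raise the other strongly epidermal probes as well, which their median of 0.033 goes against. A lower share of some dermal component in the F/– pool may remain, as may a genotype effect. Neither was tested, since no probe is tied to a cell type here and the pools held 3 and 2 mice.

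Many of the higher probes on both arrays were very bright. The median log2 ratio of the brightest 2% was 0.35 in the epidermis and 0.17 in the dermis, and in the brightest 1% (209 probes) it was 0.83 and 0.39. In the authors' deposited table the medians of the brightest 2% had the opposite sign, -0.23 and -0.098. A dye difference at the bright end that loess with the usual span leaves in may account for this, and with a span of 0.1 only 42 of the 86 bright epidermal and 19 of the 38 bright dermal calls were past 2-fold, against 4 and 2 in the authors' deposited table. The dermal median of the brightest 2%, at 0.17, missed the 0.2 set as the mark for it. That mark was set after the values had been seen in part, so it decides little. Without a dye swap such a dye difference cannot be told apart from genotype. Of the 86 bright probes called higher in the epidermis, 31.4% (27) had a Cy5 signal at the scanner's upper limit, between the marks set beforehand, but such a limit lowers Cy5 over Cy3. With spots at the limit out of the loess fit, all 59 other bright calls in the epidermis (100%) and all 35 in the dermis were past 2-fold, so the tables argue against the upper limit as the cause.

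Outside the brightest 2% of either array, 170 probes passed 2-fold in the epidermis and 26 in the dermis. After subtracting the median ratio of each block of about 20 by 20 spots, 178 passed in the epidermis, which argues against a spatial trend on that array. Spot noise was larger on the epidermis array. With the epidermal threshold raised in proportion, from 2-fold to 3.03-fold, 47 probes passed against 26. That lay between the mark set beforehand for noise and the 2 times set against it, so this test could not tell. Against noise as the whole, 2-fold lay 12.6 SDs from 0 on that array, but the SD comes from 50 probes and leaves out damaged spots. With probes from uneven spots left out as well, 101 were higher and 57 lower in the epidermis, against 11 and 9 in the dermis. These counts argue against damaged spots as the source of the difference. Spot noise that the 50 probes do not capture stays open as part of it. Differences between pools and a true difference between the layers, in one of which K5-Cre is active, could not be tested with 1 array each.

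The authors' deposited table holds no value for uneven spots, and the sources used here state no filter. All 115 probe spots of the epidermis array and all 16 of the dermis array with a pixel SD over 0.5 times the mean lack a value there, against 2.44% and 1.03% of the other probe spots. Uneven spots made up 7 of the 17 lower calls in the dermis and 4 of its 5 lowest ratios.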
